A study of Canis lupus with 20 samples.

How the data were processed

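Gene expression was measured in left atrial and left ventricular tissue of dogs 12 weeks after uninephrectomy or sham surgery, on 20 Affymetrix canine arrays, 5 in each of 4 groups, with no technical replicates. Per the labels, RNA was extracted with Trizol and 100 ng of total RNA was amplified and biotin labelled with the IVT Express kit. The deposited values are on a log2 scale; how the authors summarized, background corrected and normalized them is not given in the sources used here. They range from 0.43 to 15.0 and were used as deposited. The arrays had medians from 2.33 to 2.39 and upper quartiles from 5.10 to 5.53. No array scan files were used. Signals of genes that are off crowd at the low end, so log2 differences of dim genes are compressed or depend on the background handling.

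Of 43035 probe sets 111 controls were left out, and the 30% with the lowest mean over all arrays (mean log2 under 1.87) were not tested, which left 30047. Of the tested probe sets 12397 (41.3%) had a mean under log2 3 in each group. Gene symbols came from the supplied annotation table, which pairs 29264 probe sets with 1 symbol and 439 with several and does not list 13332. The tested probe sets cover 11423 genes with 1 symbol. NPPA, MYH6 and NR3C2 have no probe set with 1 symbol, and AGT and ACE lie below the filter, so these genes are not given.

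Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), in a fit of all 20 arrays with a mean per group and 16 residual degrees of freedom. The 5 contrasts were uninephrectomy against sham in the atrium, the same in the ventricle, the difference of these effects, and atrium against ventricle in sham and in uninephrectomized dogs. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05. The median standard error of a contrast of 2 groups was 0.11 on the log2 scale. The method was tested on simulated data with 200 probe sets changed: changes of 0.5, 1 and 2 log2 were recovered in 49.0%, 85.0% and 97.5% of probe sets for the atrial, 44.5%, 87.0% and 99.0% for the ventricular, and 13.5%, 73.0% and 95.0% for the difference contrast. The simulated values were independent and normal, with 1 mean and 1 SD per probe set. Real arrays deviate together across genes and group SDs differ, so these rates need not hold for the real data.

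Gene lists were tested with limma's camera (correlation between genes preset at 0.01) on 1 probe set per gene, the one with the highest mean, for lists with at least 5 measured genes. Of 956 list genes 688 had a probe set. The 20 pathway lists were natriuretic and stretch genes, extracellular matrix and fibrosis, renin-angiotensin-aldosterone and glucocorticoid, apoptosis, oxidative phosphorylation, fatty acid oxidation, glycolysis, calcium handling, ion channels and gap junctions, sarcomere, inflammatory cytokines and adhesion, interferon response, complement, oxidative stress, unfolded protein and heat shock response, immediate early, hypoxia and angiogenesis, phosphate with FGF23 and vitamin D, cell cycle, and ribosomal proteins. The 10 cell type lists were cardiomyocyte, fibroblast, endothelial, smooth muscle and pericyte, macrophage and monocyte, lymphocyte, neutrophil and blood, adipocyte, mesothelial and epicardial, and Schwann and neuronal. Atrial and ventricular marker lists were added for the chamber contrasts. Camera with an estimated correlation, fry, and exact permutation of the list mean per array (252 splits, smallest possible p 0.0079) were run beside it. Members were also adjusted over their list alone.

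The contrasts, lists and rules were fixed before the data were examined. The genes named are, for each uninephrectomy contrast, the 10 with the smallest p in each direction (5 for the difference), and for each chamber contrast the 10 called genes with the largest change in each direction. To these were added NPPB, COL1A1, COL3A1, TGFB1, MYH7, ATP2A2, MYL2 and MYL7 and members of the lists. The list members given as examples were chosen after their values were seen. RNA quality was judged by the mean log2 gap between 3' and middle or 5' control probe sets of ACTB, GAPDH and EEF1A. That gap followed the first component of the deviations from the group means (19.1% of variance) across 20 arrays, with a Pearson correlation of 0.924, a Spearman correlation of 0.901 and a permutation p of 1e-05, the smallest the permutations can give.

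The labels number the arrays of each group. Whether equal numbers mark the same dog was checked from the deviations of the arrays from their group means, before any blocked fit was compared. The correlations across probe sets of sham atrial and ventricular arrays of the same number were 0.463, 0.226, 0.373, 0.295 and 0.209. Each lay above 0.1, so these numbers were taken to pair the sham arrays. The pairing comes from the data, not from the labels. The 3' gap was not removed in this check. The first component of the deviations, which the gap followed, was alike in the chambers for number 1 (-22.5 in the atrium and -24.1 in the ventricle). It had the same sign for number 3 (26.9 and 39.9) and opposite signs for number 2 (3.17 and -23.8). Shared RNA quality may therefore add to some of these correlations.

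The alternatives were other dim filters, quantile normalization, a median shift per array, array weights, trend and robust fits, a fit of the 10 arrays compared, 1 probe set per gene, a fold threshold of 1.5, the replicate number as a block, and leaving out each array in turn. The 3' gap as a covariate, a block for the sham numbers alone, permutation of list means, and leaving out sham ventricular array 3 with sham atrial array 4 were added after the data were seen. The arrays were split into groups in 100 ways with a fixed seed, the real grouping among them. Python 3.11.15 with matplotlib 3.10.9 drew the figures.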

Results

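The series covers left atrial and left ventricular tissue of dogs examined 12 weeks after removal of the right kidney (uninephrectomy) or a sham operation. Gene expression was measured on Affymetrix canine arrays in 4 groups of 5 arrays, sham atrium, uninephrectomized atrium, sham ventricle and uninephrectomized ventricle, with 1 array per tissue sample. The design text assigns 6 dogs to each operation, of which 5 samples per chamber were put on arrays. The comparisons below ask what the loss of renal mass does to gene expression in each chamber, whether the chambers differ in that response, and how the chambers differ from each other. Signals are log2 values, and differences are given as log2 difference ± standard error with n = 5 arrays per group unless stated. The median standard error of a difference between 2 groups was 0.11, which gives a 95% confidence interval of about 0.22 on either side.

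In the left atrium the named genes with the smallest p after uninephrectomy included POLR2C, a subunit of RNA polymerase II, and SERPINE2, a secreted inhibitor of thrombin and plasminogen activators, but no gene passed the test. POLR2C had a mean of 5.48 ± 0.07 (SD) in uninephrectomized and 4.58 ± 0.31 (SD) in sham atria, a difference of 0.90 ± 0.18 (adjusted p = 0.631). SERPINE2 differed by 1.44 ± 0.33, EXT2, an enzyme of heparan sulfate synthesis, by 0.38 ± 0.08, and FABP3, the heart fatty acid binding protein, by 0.41 ± 0.10. On the lower side stood CDC5L, a splicing factor, at -0.89 ± 0.19, TLN1, which links integrins to actin, at -0.83 ± 0.19, and MAPT, the microtubule protein tau, at -0.59 ± 0.14. Of the other named genes, CAVIN3, ANKFY1, SLC27A3, ZNF18, SUPT7L and DGKA had positive and CENPS, TUT7, TRAFD1, ANKRD54, COPS2, TIMM9 and DKC1 negative differences, all with adjusted p = 0.631. Some are dim: ANKFY1, CENPS, ANKRD54 and DKC1 lay under log2 3 in each atrial array. TRAFD1 ranged from 2.19 to 3.04 in the atria, SUPT7L from 2.27 to 3.52 and MAPT from 2.55 to 3.48. Limma called 0 of 30047 probe sets, with 2010 at an unadjusted p under 0.05 where 1502 are expected by chance. When sham atrial array 5 was left out, 1 probe set without a gene symbol was called (log2 difference -0.95, adjusted p = 0.0411).

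Genes of the extracellular matrix lay higher in uninephrectomized than in sham atria as a list. Of the 47 measured members 36 had positive differences, with a median of 0.18. They include FBLN1 (fibulin-1) at 0.72 ± 0.27, PCOLCE, an enhancer of procollagen processing, at 0.85 ± 0.35, VCAN (versican) at 1.04 ± 0.45 and THBS2 (thrombospondin-2) at 0.67 ± 0.20. The THBS2 signal is dim, at 2.63 ± 0.63 (SD) in uninephrectomized and 1.96 ± 0.12 (SD) in sham atria. The list passed camera at adjusted p = 6.82e-05 with the preset correlation, and had adjusted p = 0.609 with an estimated correlation. Fibroblast markers followed, with 14 of 15 members positive, DCN (decorin) at 0.32 ± 0.15 and LUM (lumican) at 0.41 ± 0.20. That list passed at adjusted p = 0.000512, and had adjusted p = 0.612 with an estimated correlation. The fibroblast list shares 6 of its genes with the matrix list, COL1A1, COL1A2, COL3A1, DCN, FBLN1 and LUM. Complement genes were positive in 15 of 19 members, with a median of 0.21, CLU (clusterin) at 0.71 ± 0.25, C6 at 3.57 ± 1.24 and C1QA at 0.50 ± 0.22. They passed at adjusted p = 0.00394, and had adjusted p = 0.609 with an estimated correlation. C6 lies far above the list median and varied widely, at 7.31 ± 2.77 (SD) in uninephrectomized and 3.74 ± 1.78 (SD) in sham atria. The complement list shares C1QA, C1QB and C1QC with the macrophage and monocyte list and C7 with the fibroblast list. No member of the matrix, fibroblast and complement lists was called over all probe sets or adjusted over the list alone. Averaged per array, the matrix list differed by 0.27 (95% confidence interval -0.10 to 0.64), the fibroblast list by 0.31 (-0.18 to 0.80) and the complement list by 0.40 (-0.03 to 0.83). Exact permutation of these array means gave p = 0.127, 0.198 and 0.0794. Over the same arrays the cardiomyocyte list differed by 0.02. The mean 3' gap of the control probe sets, a measure of RNA quality, was 1.10 ± 0.26 (SD) against 1.19 ± 0.19 (SD), exact permutation p = 0.532. Leaving out sham atrial array 1 raised the adjusted p of the complement and fibroblast lists to 0.107 and 0.104, and leaving out uninephrectomized atrial array 4 raised that of the complement list to 0.107. Leaving out sham atrial array 5 gave 7 called lists.

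A few atrial genes passed the test when adjusted over the list alone but not over all probe sets. That adjustment is not corrected for the 30 lists tested, so some members can pass by chance. FABP3 did so among the fatty acid oxidation genes (list adjusted p = 0.0137) and among the cardiomyocyte markers (0.00643). BNIP3L, a mitochondrial protein of the BCL2 family, differed by 0.53 ± 0.13 (apoptosis list, 0.0176), and ENO1, the glycolytic enzyme enolase 1, by 0.30 ± 0.08 (glycolysis list, 0.0277). NUSAP1, a spindle protein, stood at 0.98 ± 0.25 (cell cycle list, 0.0229), and NRP2, a receptor for vascular endothelial growth factor C, at -0.59 ± 0.16 (hypoxia and angiogenesis list, 0.0401). The NRP2 signal is dim, at 2.80 in uninephrectomized and 3.39 in sham atria. HSD11B1, which regenerates active glucocorticoid, had a mean of 6.88 ± 2.28 (SD) in uninephrectomized and 4.21 ± 0.15 (SD) in sham atria, and its difference of 2.67 ± 0.97 passed neither test (adjusted p = 0.679, list adjusted p = 0.259). Among the genes always given, NPPB (B-type natriuretic peptide) had a mean of 10.53 ± 0.85 (SD) in uninephrectomized and 9.33 ± 2.55 (SD) in sham atria (adjusted p = 0.805). The NPPB difference was 0.22 ± 0.56 without sham atrial array 3 and 1.84 ± 0.78 without sham atrial array 5. COL1A1 differed by 0.28 ± 0.31, COL3A1 by 0.27 ± 0.32, TGFB1 by -0.22 ± 0.12, MYH7 by -0.05 ± 0.10, ATP2A2 by -0.06 ± 0.07, MYL2 by 0.91 ± 0.57 and MYL7 by -0.09 ± 0.13. The atrial SDs of MYL2 were 1.59 in uninephrectomized and 1.05 in sham dogs, a spread that its pooled standard error understates. The other 27 of the 30 lists had camera adjusted p between 0.157 and 0.979 in the atrium.

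**Figure D1:**
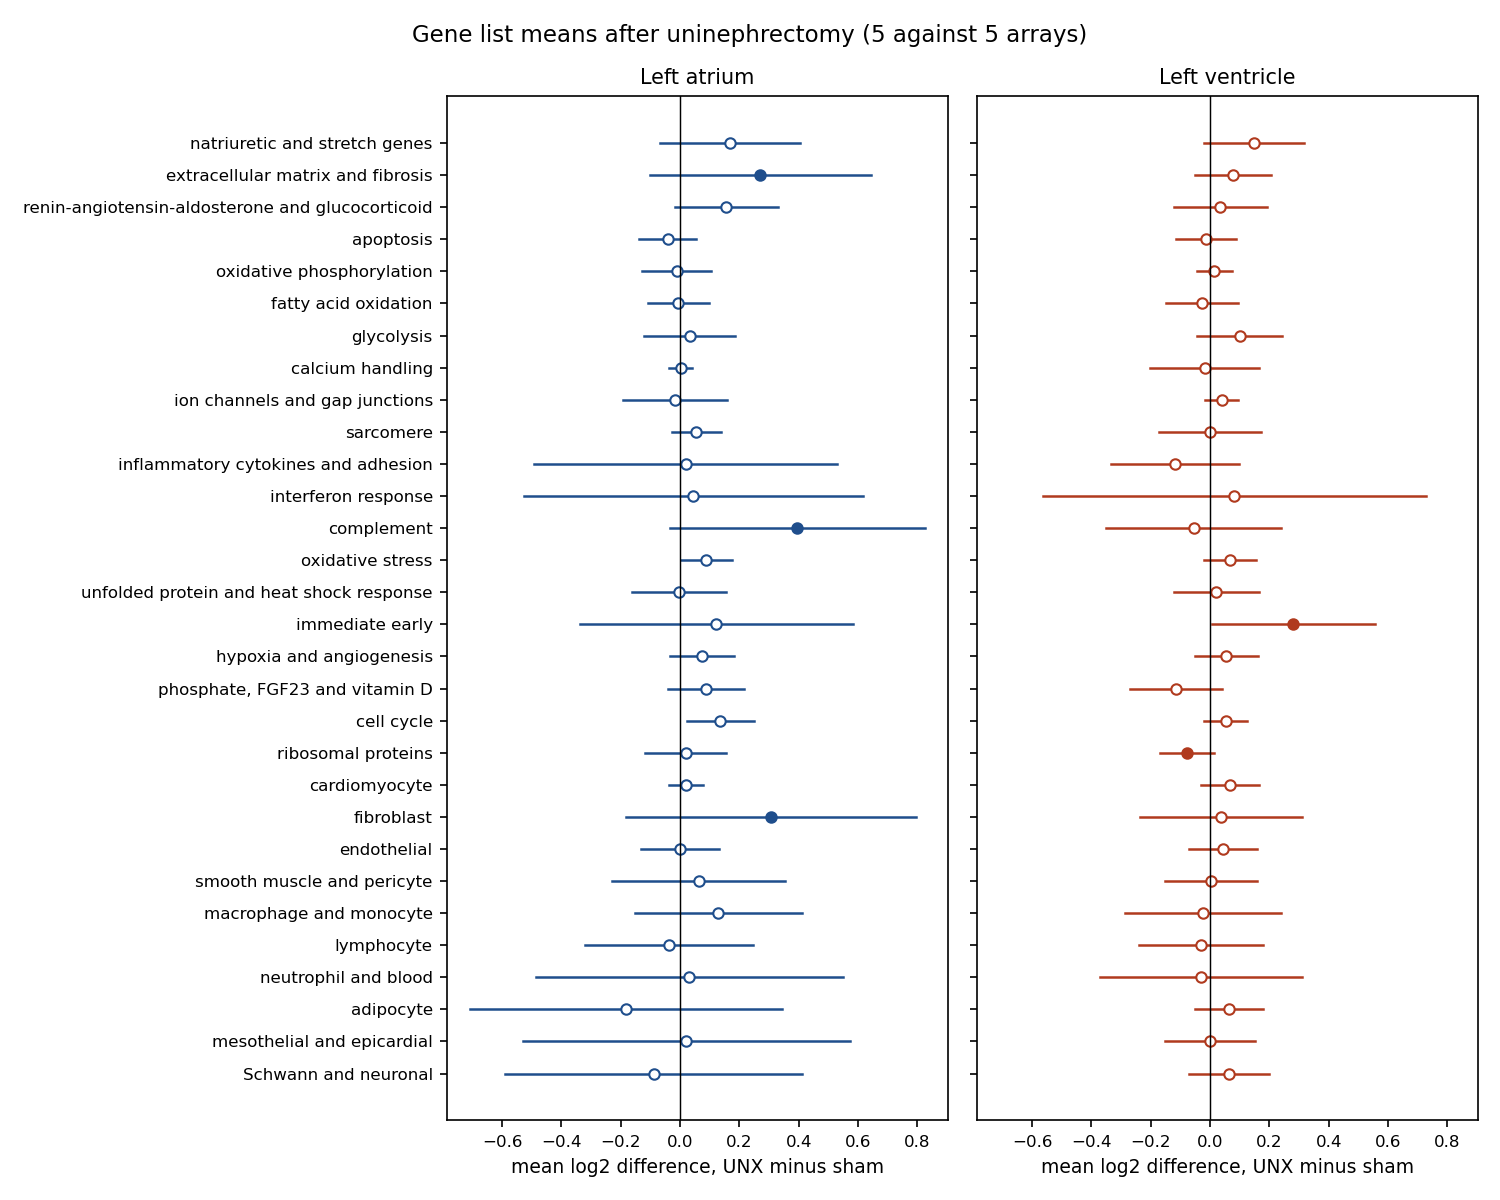
Mean difference of each gene list between uninephrectomized (UNX) and sham dogs on the log2 scale, left atrium on the left and left ventricle on the right; points are the difference of the mean list signal of 5 against 5 arrays, lines its 95% confidence interval, and filled points lists called by camera with the preset correlation. The matrix, complement and fibroblast lists stand at 0.27, 0.40 and 0.31 in the atrium with intervals that include 0, and the ribosomal list at -0.08 in the ventricle.

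In the left ventricle VWA8, a mitochondrial ATPase domain protein, had the smallest p of the named genes, with a mean of 7.61 ± 0.47 (SD) in uninephrectomized and 6.25 ± 0.41 (SD) in sham dogs. It did not pass the test (1.35 ± 0.23, adjusted p = 0.242). BDH1, an enzyme of ketone body metabolism, differed by 0.81 ± 0.19, FLNC, the sarcomeric filamin C, by 0.86 ± 0.21, and ABLIM1, an actin-binding protein, by 0.96 ± 0.23, each with adjusted p = 0.480. The FLNC value comes from a weak probe set (means 4.17 and 3.31), and the brightest FLNC probe set differed by 0.39 ± 0.22 (adjusted p = 0.758). On the lower side stood LRRC4 at -0.95 ± 0.22, PRPF4B, a kinase of the spliceosome, at -0.37 ± 0.08 and PSME2, a proteasome activator subunit, at -0.33 ± 0.08. CDC73, of the PAF1 transcription complex, differed by 0.52 ± 0.11 (adjusted p = 0.338). The remaining named genes were PHLDB1, PIWIL4, MPI, PHC1 and PARP3 with positive and CNPPD1, MPHOSPH9, NUDCD1, IMMP2L, DOCK8, UHMK1 and TCTN2 with negative differences. Of these, PHLDB1, PIWIL4, PHC1, CNPPD1 and DOCK8 lay under log2 3 in each ventricular array, and PARP3 ranged from 2.33 to 3.06. Limma called 0 of 30047 probe sets, with 2005 at an unadjusted p under 0.05. Leaving out sham ventricular array 1 gave 4 called probe sets, of which CDC73 (0.61, adjusted p = 0.0418) has a symbol. Without uninephrectomized ventricular array 4 VWA8 was called (1.54, adjusted p = 0.0462), and without uninephrectomized ventricular array 1 a probe set that has no symbol (-6.95, adjusted p = 0.0451).

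Ribosomal protein genes lay slightly lower in uninephrectomized than in sham ventricles, with 42 of 47 members negative and a median of -0.09. RPL12 stood at -0.22 ± 0.07 and RPL7 at -0.17 ± 0.07, and no member was called over all probe sets or adjusted over the list alone. The list passed camera at adjusted p = 8.20e-06 with the preset correlation, and had adjusted p = 0.835 with an estimated correlation. In the same arrays the mean 3' gap of the control probe sets was 1.14 ± 0.15 (SD) in uninephrectomized and 1.42 ± 0.27 (SD) in sham ventricles (exact permutation p = 0.0635, adjusted p = 0.254 over 16 such comparisons). The GAPDH part of it was 1.62 in uninephrectomized and 1.81 in sham ventricles (exact permutation p = 0.0159, adjusted p = 0.127). With the mean gap as a covariate the list had adjusted p = 0.135. Immediate early genes, which are induced within minutes of a stimulus, were positive in 15 of 19 members, with FOS at 0.79 ± 0.33, KLF6 at 0.22 ± 0.10 and ATF3 at 0.94 ± 0.52. They passed camera at adjusted p = 0.0292, had adjusted p = 0.835 with an estimated correlation, and 0 members were called over all probe sets or adjusted over the list alone. Averaged per array, the ribosomal list differed by -0.08 (95% confidence interval -0.17 to 0.01) and the immediate early list by 0.28 (0.01 to 0.55). Exact permutation of the array means gave p = 0.0952 and 0.0635. The immediate early call was lost when any of 6 ventricular arrays was left out. Its adjusted p was 0.0749, 0.0586 and 0.0697 without sham arrays 1, 2 and 5, and 0.0560, 0.216 and 0.103 without uninephrectomized arrays 2, 3 and 5.

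The atrial light chain gene MYL7 passed the ventricular test when adjusted over the sarcomere list alone (list adjusted p = 0.0363), at -0.51 ± 0.13, but not over all probe sets (adjusted p = 0.551). As in the atrium, the list adjustment is not corrected for the number of lists. RCAN1, a regulator of calcineurin, differed by 1.18 ± 0.35 (list adjusted p = 0.0676) and NQO1, an antioxidant enzyme, by 0.45 ± 0.13 (0.0786). NPPB stood at 0.71 ± 0.83 (adjusted p = 0.896), COL1A1 at -0.17 ± 0.31, COL3A1 at 0.04 ± 0.32, TGFB1 at -0.01 ± 0.12, MYH7 at 0.06 ± 0.10, ATP2A2 at -0.06 ± 0.07 and MYL2 at -0.11 ± 0.57. NPPB was dim here, at 3.68 ± 0.74 (SD) in uninephrectomized and 2.97 ± 0.34 (SD) in sham ventricles. Its pooled standard error carries the wide spread of sham atria (SD 2.55). The ventricular SDs of MYL2 were 0.09 in uninephrectomized and 0.28 in sham dogs, and its pooled standard error carries the atrial spread. The other 28 lists had camera adjusted p between 0.211 and 0.991 in the ventricle.

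**Figure D2:**
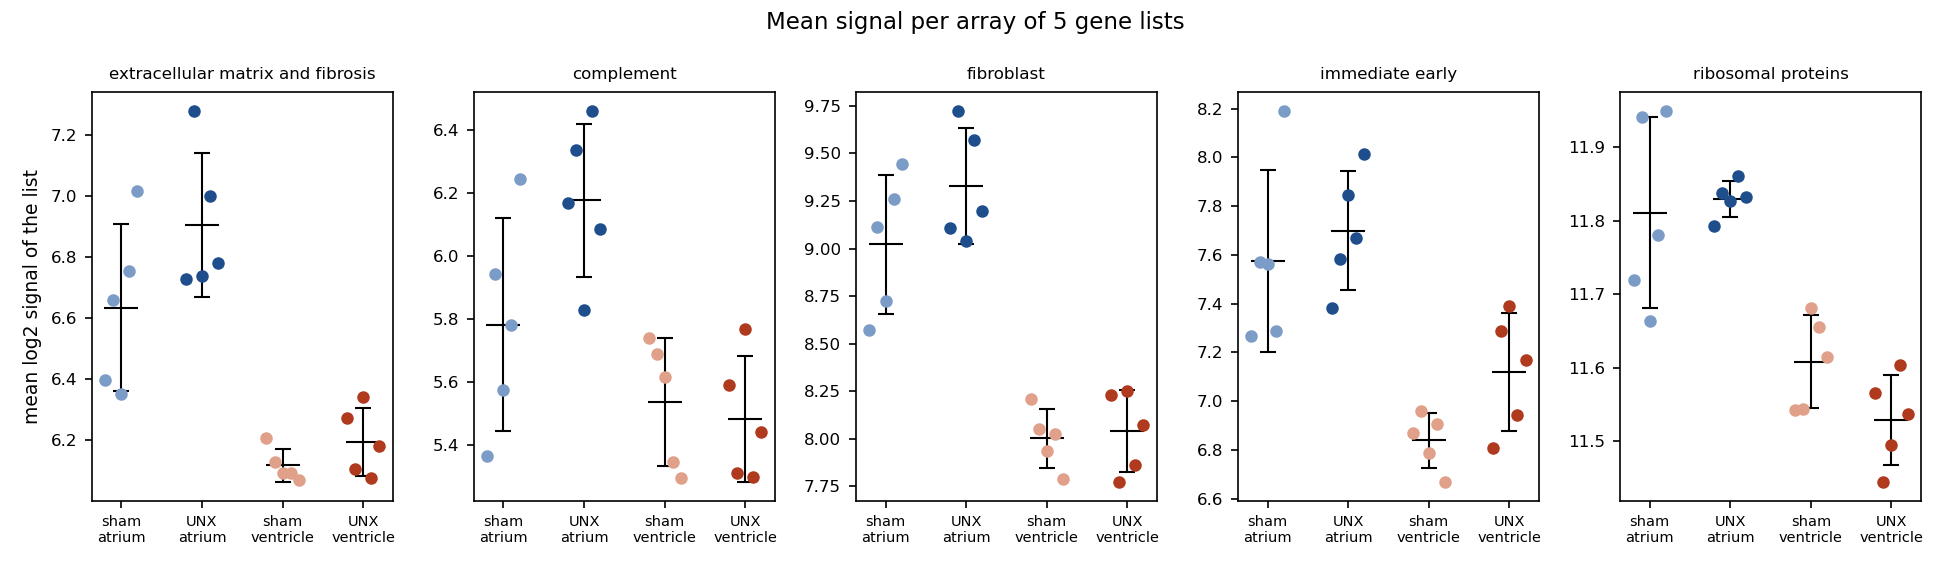
Mean log2 signal per array of the 5 gene lists called by camera with the preset correlation, in sham and uninephrectomized (UNX) atria and ventricles; points are arrays, bars the mean and SD of 5 arrays, and each panel has its own axis, which does not start at 0. Sham and uninephrectomized arrays overlap within a chamber in each panel, and the atrial matrix list has a mean of 6.91 in uninephrectomized and 6.63 in sham dogs.

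The response to uninephrectomy differed detectably between the chambers for no gene. VWA8 had a contrast of -1.41 ± 0.33, from 3.83 against 3.89 in the atrium and 7.61 against 6.25 in the ventricle. AGPAT4, an acyltransferase of phospholipid synthesis, stood at 0.82 ± 0.19, DRG2, a GTP-binding protein, at -0.81 ± 0.21, and IFT74, NGDN, GDAP2 and RFESD were positive while PHLDB1, MFSD10 and TRAFD1 were negative. PHLDB1 and MFSD10 lay under log2 3 in each array, and AGPAT4 in each ventricular array. Limma called 0 of 30047 probe sets for the interaction, with 893 at an unadjusted p under 0.05 where 1502 are expected by chance. That expectation assumes independent arrays. The sham arrays pair by number across the chambers and this fit had no block, so its p-values may be too large. Across probe sets the surgery effects in atrium and ventricle had a Pearson correlation of 0.455. Deviations that the paired sham arrays share enter both effects, so this correlation can arise without a shared response to the surgery. As lists, ribosomal proteins (45 of 47 members positive), complement genes (14 of 19) and matrix genes (33 of 47) lay higher in the atrial than in the ventricular response, by 0.10, 0.45 and 0.19 on average. The medians were 0.09, 0.21 and 0.18, and the complement gene C6 alone had a contrast of 3.24 ± 1.75. The ribosomal difference came mostly from the ventricle, where the 3' gap had a mean of 1.42 in sham and 1.14 in uninephrectomized dogs (exact permutation p = 0.0635). With that gap as a covariate the ribosomal list had adjusted p = 0.0148. Without it the 3 lists passed camera at adjusted p = 1.08e-05, 0.00296 and 0.0337, and had adjusted p = 0.927, 0.652 and 0.927 with an estimated correlation. The remaining 27 lists had adjusted p between 0.0530 and 0.979. Without uninephrectomized atrial array 4 the complement list had adjusted p = 0.0562 and the matrix list 0.0984. The matrix call was also lost without sham atrial array 1 or 3 (0.239 and 0.427) and uninephrectomized atrial array 2 (0.417). The same held without sham ventricular array 1, 2 or 5 (0.166, 0.0889 and 0.0505) and uninephrectomized ventricular array 2, 4 or 5 (0.0774, 0.101 and 0.0747), with arrays shifted to the same median (0.0523) and with array weights (0.0754). Camera called 1 list without uninephrectomized atrial array 4, 6 without sham atrial array 5, and 5 without uninephrectomized atrial array 1, sham ventricular array 3 or uninephrectomized ventricular array 1.

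The chambers themselves differed strongly. In sham dogs MYL2, the ventricular regulatory myosin light chain, fell from 14.66 ± 0.28 (SD) in the ventricle to 3.81 ± 1.05 (SD) in the atrium (log2 difference -10.85 ± 0.57, 1845-fold lower, adjusted p = 9.94e-11). MYL3, the ventricular essential light chain, was 203-fold lower at -7.66 ± 0.62. IRX5, a homeobox factor of ventricular patterning, stood at -5.70 ± 0.41, and UCP3, a mitochondrial uncoupling protein, at -4.67 ± 0.41. In the other direction CTNNA2, an alpha catenin of cell junctions, rose to 10.79 ± 0.14 (SD) in the atrium from 2.04 ± 0.41 (SD) in the ventricle (8.75 ± 0.14, 432-fold higher, adjusted p = 9.84e-19). NR2F1, the orphan nuclear receptor of atrial identity, was higher by 6.81 ± 0.13, NPPB by 6.36 ± 0.83, MYL4, the atrial essential light chain, by 5.88 ± 1.07, and HPGDS, a prostaglandin D synthase, by 6.57 ± 0.51. MYL4 ranged from 4.69 to 10.09 among the sham ventricular arrays, so the size of its difference depends on the arrays included. HSD17B13, ETNPPL, CRYM, TOX and TPM4 completed the genes higher in the atrium, with log2 differences from 6.06 to 8.52. For TPM4 this rests on 1 called probe set of 6, of which 4 had the same sign. PLPPR5, ANKRD23, OR51F23, PABPC1L, MPPED2 and LEAP2 completed those lower, with log2 differences from -4.43 to -5.05. Limma called 6257 of 30047 probe sets, 3367 higher and 2890 lower in the atrium, of which 2884 differed by at least 1.5-fold and 1251 by at least 2-fold. The dim chamber of such a gene lies near the low end of the signal scale, where the handling of background sets the size of the fold.

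**Figure D3:**
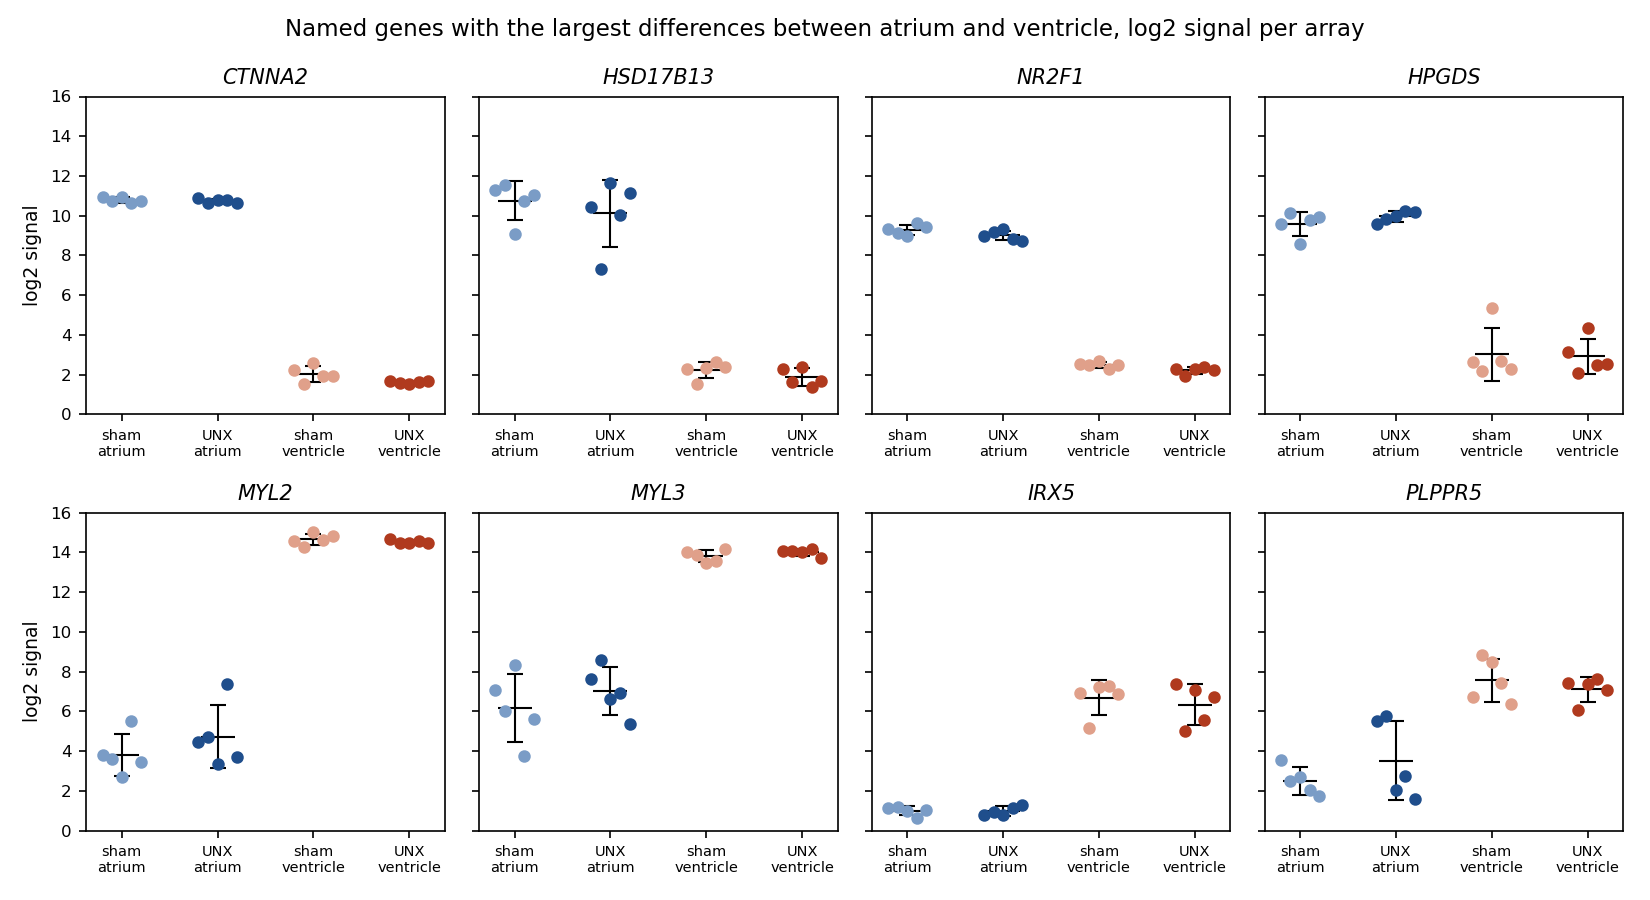
Log2 signal per array of the 4 named genes with the largest difference in each direction between left atrium and left ventricle of sham dogs, shown for sham and uninephrectomized (UNX) dogs; points are arrays, bars the mean and SD of 5 arrays. CTNNA2 has a mean of 10.79 in sham atria and 2.04 in sham ventricles, and MYL2 of 3.81 and 14.66.

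Of the marker lists fixed for the chambers, atrial markers were higher in the sham atrium, with 11 of 16 members called higher and 0 lower (13 when adjusted over the list alone). They include PAM, the peptide-amidating enzyme, at 2.68 ± 0.06, DKK3 at 5.06 ± 0.30 and MYL7 at 2.02 ± 0.13 (camera adjusted p = 1.04e-11, and 0.000237 with an estimated correlation). Ventricular markers were lower, with 9 of 15 called lower and 2 higher, FHL2 at -3.02 ± 0.27 among them (9.18e-05, and 0.00555 with an estimated correlation). Of 32 fatty acid oxidation genes 18 were called lower and 2 higher, with MLYCD, malonyl-CoA decarboxylase, at -1.12 ± 0.09, FABP3 at -1.10 ± 0.10 and ACSL1, an acyl-CoA synthetase, at -0.75 ± 0.09 (6.62e-07, and 0.0242 with an estimated correlation). Of 56 oxidative phosphorylation genes 21 were called lower and 0 higher (31 adjusted over the list alone), with NDUFV3 at -0.45 ± 0.08 and SDHA at -0.38 ± 0.08 (6.90e-09, but adjusted p = 0.472 with an estimated correlation). Sarcomere genes were lower in 15 of 29 members and higher in 3 (1.27e-05, and 0.0338 with an estimated correlation). Cardiomyocyte markers, which share 9 genes with that list, were lower in 10 of 15, TNNI3 at -0.38 ± 0.06 and MB, myoglobin, at -0.38 ± 0.07 among them (7.51e-06, and 0.0338 with an estimated correlation).

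The matrix, fibroblast, ribosomal protein and immediate early lists were called higher in the sham atrium with the preset correlation, but not with an estimated correlation. Of 47 matrix genes 17 were called higher and 2 lower (21 and 2 adjusted over the list alone), with COL14A1 at 3.88 ± 0.46, COL1A2 at 1.49 ± 0.22, COL1A1 at 1.42 ± 0.31 and COL3A1 at 1.35 ± 0.32, while TGFB3 was lower at -0.60 ± 0.11. That list passed camera at adjusted p = 0.000235, but had adjusted p = 0.476 with an estimated correlation. Of 15 fibroblast markers 9 were called higher and 0 lower (11 adjusted over the list alone), with OGN, osteoglycin, at 3.57 ± 0.28 and MFAP5 at 0.92 ± 0.19 (1.29e-06, but adjusted p = 0.307 with an estimated correlation). Ribosomal protein genes were called higher in 28 of 47 members, by small amounts such as 0.33 ± 0.06 for RPL13A (6.90e-09, but adjusted p = 0.476 with an estimated correlation). The mean 3' gap was 1.19 ± 0.19 (SD) in these atria and 1.42 ± 0.27 (SD) in these ventricles (exact permutation p = 0.159). Of its parts the EEF1A gap differed most, at 0.98 and 1.62 (exact permutation p = 0.0238, adjusted p = 0.127). Immediate early genes were called higher in 6 of 19 members, FOS at 3.05 ± 0.33, EGR1 at 4.26 ± 0.53 and NR4A1 at 1.83 ± 0.26 (0.00176, but adjusted p = 0.476 with an estimated correlation). Camera did not call the other 22 lists, at adjusted p from 0.0873 to 0.959. Natriuretic and stretch genes had 4 called higher, NPR3, a clearance receptor, at 2.20 ± 0.25 among them, and 5 lower. MYH7, the beta myosin heavy chain, was lower at -0.68 ± 0.10, while TGFB1 at -0.19 ± 0.12 (adjusted p = 0.303) and ATP2A2 at 0.13 ± 0.07 (0.220) did not pass. ATP2A2 did pass after quantile normalization (0.32 ± 0.05, adjusted p = 0.000284) and with the 3' gap as a covariate (0.20 ± 0.07, adjusted p = 0.0463). In the main fit only 1 of its 2 tested probe sets had this sign.

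For the rest of these lists the number of genes called higher and lower was 3 and 5 of 27 for calcium handling, 2 and 6 of 22 for glycolysis, and 5 and 4 of 25 for ion channels and gap junctions. Among the channels KCNJ3, a subunit of the atrial acetylcholine-gated potassium channel, stood at 2.84 ± 0.24 and GJA5 (a connexin) at 3.26 ± 0.63. The counts were 4 and 2 of 20 for renin-angiotensin-aldosterone and glucocorticoid genes, with EDNRA, an endothelin receptor, at 0.99 ± 0.09. They were 2 and 4 of 29 for apoptosis, 4 and 2 of 39 for inflammatory cytokines and adhesion and 2 and 3 of 27 for the interferon response. They were 4 and 0 of 19 for complement, 4 and 4 of 28 for oxidative stress, 2 and 8 of 32 for the unfolded protein and heat shock response, with HSPB7, a small heat shock protein of the heart, at -1.23 ± 0.09, and 6 and 3 of 29 for hypoxia and angiogenesis. Phosphate, FGF23 and vitamin D genes had 1 and 2 of 15, and cell cycle genes 7 and 2 of 25. Among cell types the counts were 0 and 3 of 17 for endothelial cells, with VWF, von Willebrand factor, at -0.59 ± 0.08. They were 4 and 1 of 15 for smooth muscle and pericytes, with TAGLN, transgelin, at 2.42 ± 0.30, and 6 and 2 of 18 for adipocytes, with ADIPOQ, adiponectin, at 3.83 ± 0.83 and CD36 at -0.99 ± 0.13. Macrophage and monocyte markers had 0 and 0 of 18, lymphocyte markers 0 and 1 of 10, neutrophil and blood markers 0 and 0 of 7, mesothelial and epicardial markers 0 and 1 of 5, and Schwann and neuronal markers 3 and 1 of 14.

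In uninephrectomized dogs the chambers differed in many of the same genes. MYL2 was lower in the atrium, at -9.83 ± 0.57, as was MYL3, at -6.98 ± 0.62. CTNNA2 was higher by 9.11 ± 0.14, MYL4 by 6.88 ± 1.07 and NPPB by 6.85 ± 0.83. MYL4 ranged from 3.66 to 10.30 among the uninephrectomized ventricular arrays. LEAP2 stood at -5.95 ± 0.47, ANKRD23 at -5.72 ± 0.21, MYOT, the Z-disc protein myotilin, at -5.69 ± 0.61 and IRX5 at -5.36 ± 0.41, and DPP6, FGF13, FHIT and UCP3 had log2 differences from -4.59 to -5.22. HSD17B13, HPGDS, NR2F1, ETNPPL, TOX, CRYM and TPM4 were higher by 6.25 to 8.24. Limma called 8190 of 30047 probe sets, 4429 higher and 3761 lower in the atrium. Of the 6257 called in sham dogs 5077 were called in the same direction here, where 858 are expected of independent calls, and 0 in the opposite direction. The log2 differences of both comparisons had a Pearson correlation of 0.942 and a Spearman correlation of 0.838 across probe sets, which are not independent replicates. A call in 1 surgery group alone does not show that the chambers differ otherwise there, since the interaction test called 0 probe sets.

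Camera called 11 of 32 lists in uninephrectomized dogs, the 10 of the sham comparison and complement. Of the complement genes 9 of 19 were called higher, with CFI at 2.44 ± 0.29, CLU at 1.78 ± 0.25 and C1S at 1.13 ± 0.25 (adjusted p = 0.00394, but adjusted p = 0.395 with an estimated correlation). Atrial markers (10 of 16 called higher, 0 lower), ventricular markers (10 of 15 lower, 3 higher), fatty acid oxidation (17 of 32 lower, 1 higher), sarcomere (17 of 29 lower, 3 higher) and cardiomyocyte markers (10 of 15 lower, 0 higher) also passed with an estimated correlation, at adjusted p of 0.000554, 0.00715, 0.0313, 0.0304 and 0.0313. Matrix genes (22 of 47 called higher, 5 lower), fibroblast markers (12 of 15, 0 lower), ribosomal proteins (37 of 47, 0 lower), immediate early genes (7 of 19, 0 lower) and oxidative phosphorylation (28 of 56 lower, 0 higher) did not, at adjusted p = 0.348, 0.248, 0.348, 0.601 and 0.348 with an estimated correlation. COL1A1 was higher by 1.87 ± 0.31, COL3A1 by 1.58 ± 0.32 and MYL7 by 2.44 ± 0.13, while MYH7 at -0.80 ± 0.10 and TGFB1 at -0.40 ± 0.12 (adjusted p = 0.0198) were lower. The mean 3' gap was 1.10 ± 0.26 (SD) in these atria and 1.14 ± 0.15 (SD) in these ventricles (exact permutation p = 0.738). Its parts went in opposite directions. The GAPDH gap was 1.77 in atria and 1.62 in ventricles (exact permutation p = 0.0159, adjusted p = 0.127), and the EEF1A gap 0.89 and 1.31 (exact permutation p = 0.0873). The immediate early call was lost with a stricter filter on dim probe sets (adjusted p = 0.0726). That of TGFB1 was lost in a fit of the 10 arrays alone (0.0558) and without uninephrectomized atrial array 1 or 3 (0.0537 and 0.0568) or uninephrectomized ventricular array 4 or 5 (0.0545 and 0.0567).

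**Figure D4:**
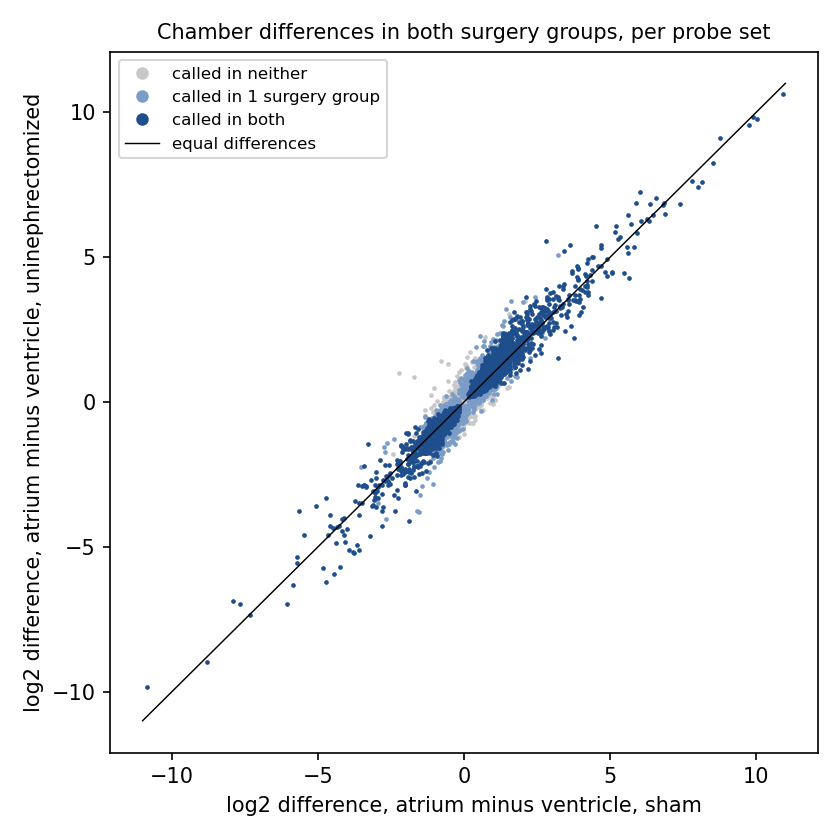
Log2 difference between left atrium and left ventricle of each tested probe set in sham dogs (horizontal axis) and in uninephrectomized dogs (vertical axis); each point is a probe set, colours show whether limma called it in neither, 1 or both of the groups, and the line marks equal differences. The 5077 probe sets called in both lie on the same side of 0 in both groups.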

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

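Of the tests in this part, the search for another order of the uninephrectomized arrays, the tests of the unnamed probe set and the tests with the 3' gap were chosen after the data were seen, and the cell share and regrouping tests before their results.

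In 18 of 350 groups of 5 arrays tested, 1 array lay apart from the other 4, where chance alone gives about 1 in 20, or 17.5. An array counted when its gap to the nearest array was over 0.71 of the range of the group. Such a gap can be small, as for cardiomyocyte markers in sham atrial array 5, at 12.308 against 12.355 in the nearest array. Among list means, uninephrectomized ventricular array 5 was low for glycolysis (9.03) and oxidative stress (8.19), sham atrial array 5 was low for cardiomyocyte markers (12.3), and Schwann and neuronal markers were high in sham atrial array 4 (4.64) and low in sham ventricular array 5 (3.25). Among genes named in the atrium, POLR2C was high in uninephrectomized array 3 (5.59), EXT2 in array 2 (8.30) and MAPT in array 4 (3.04), TRAFD1 was low in array 3 (2.19) and TLN1 in array 1 (3.56), and SUPT7L was high in sham array 1 (2.71). In sham ventricles FLNC was low in array 3 (2.71), NUDCD1 low (6.97), GDAP2 high (5.59) and IRX5 low (5.14) in array 2, and HPGDS was high in array 3 (5.36). LEAP2 was low in sham atrial array 5 (3.20), and TPM4 was high in uninephrectomized ventricular array 4 (5.37).

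The effect of uninephrectomy on matrix, complement and ribosomal protein genes was higher in the atrium than in the ventricle, by 0.19, 0.45 and 0.10 on average (medians 0.18, 0.21 and 0.09). For ribosomal proteins the atrial effect was 0.02 and the ventricular effect -0.08, and for complement 0.40 and -0.06. The difference between chambers passed camera with the preset correlation, and had adjusted p = 0.927, 0.652 and 0.927 with an estimated correlation.

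Arrays of uninephrectomized dogs with the same number did not deviate together in the 2 chambers, with a mean correlation across probe sets of -0.03. The same dogs numbered in another order may explain this: the order chosen on the other probe sets ranked 1 of 120 on 151 probe sets that vary between the sham dogs (mean correlation 0.890, against 0.536 for the next order). A different dog in either chamber is argued against by the lowest pair, at 0.841. Shared RNA quality, as the 3' gap measures it, is argued against by a mean correlation of 0.849 on these 151 probe sets after the gap was removed (lowest pair 0.747). The other order remains a hypothesis, found and tested on the same arrays, and no fit used it.

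A probe set without a gene symbol was lower after uninephrectomy in both chambers, by a log2 difference of -5.37 ± 1.19 in the atrium (adjusted p = 0.631, exact permutation p = 0.0317) and -5.76 ± 1.19 in the ventricle (adjusted p = 0.338, exact permutation p = 0.0079, the smallest possible); it was singled out after its values were seen. Lowering by the surgery in every dog is argued against by 2 of 10 uninephrectomized arrays, which lay within 1 log2 of the sham range (8.05 in atrial array 3 and 8.33 in ventricular array 1). In the other order described above these 2 arrays would be 1 dog of 5. The remaining 8 arrays lay at least 4 log2 below it, so a candidate explanation is an on and off state that differs between dogs and fell unevenly on the groups. The exact p-values are not adjusted for that choice, and a contribution of the surgery stays open.

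With the preset correlation, fibroblast, matrix and complement lists were called higher in the atrium, and ribosomal proteins lower and immediate early genes higher in the ventricle, but they had adjusted p = 0.612, 0.609, 0.609, 0.835 and 0.835 with an estimated correlation. With the 3' gap as a covariate the ribosomal shift kept 59.1% of its size (95% confidence interval -7.46 to 126; 32.6 to 73.2 without each array in turn, the lowest without uninephrectomized ventricular array 2), which leaves RNA quality open. The fibroblast shift kept 98.1% (95% confidence interval 78.5 to 118, and 81.8 to 101 without each array in turn). That argues against RNA quality, as this gap measures it, as the source of the observed shift. The intervals of the ribosomal and fibroblast percentages carry the spread of the removed part alone and take the shift as fixed. The fibroblast shift itself has a 95% confidence interval of -0.18 to 0.80, which includes 0. A lower share of cardiomyocytes in the atrial samples would raise fibroblast and endothelial markers alike. Their shifts differed by 0.31 (95% confidence interval -0.15 to 0.76, exact permutation p = 0.183), which leaves it open. The endothelial list itself differed by -0.001 (-0.13 to 0.13), which argues against a shared rise as large as 0.31 but not a smaller one. The smooth muscle and pericyte list differed by 0.06 (-0.23 to 0.35) and the cardiomyocyte list by 0.02 (-0.04 to 0.08). A response to the surgery itself stays open too.

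The arrays compared were split in 100 ways, the real grouping among them, so each count of splits as large includes it. For probe sets after uninephrectomy the regrouping decides nothing, since any split gives at least the real counts of 0, 0 and 0 (100 of 100 each); the highest other counts were 56 in the atrium, 16 in the ventricle and 4 for the difference. Chance is argued against for the chambers, with 6257 in sham dogs against 831 and 8190 in uninephrectomized dogs against 3. The real grouping was the only 1 of 100 splits as large. These splits exchange arrays freely, although the sham arrays pair by number. For the number of lists called with the preset correlation chance cannot be excluded: 3 in the atrium against 11 (68 splits as large), 2 in the ventricle against 9 (71), 3 for the difference against 12 (65), and 10 and 11 for the chambers against 13 and 13 (22 and 22). This concerns the number of lists alone, and 5 and 5 chamber lists also passed with an estimated correlation. At least 1 list was called in 91 other splits for the atrium, 89 for the ventricle and 89 for the difference. The median counts were 4, 3 and 3. The estimated correlation between genes was 0.198 for matrix, 0.455 for fibroblast, 0.218 for complement, 0.501 for ribosomal and 0.279 for immediate early genes. These lie above the preset of 0.01, and a preset that is too low makes camera p-values too small. Whether this accounts for the calls in other splits was not tested. Among the 16 splits of the sham arrays that part all 5 pairs, the highest other count was 4 probe sets and 13 lists. So few splits cannot exclude chance by their number alone.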

How the results depend on the processing

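The 3' gap covariate, the sham-only block, the permutation of list means and the fit without sham ventricular array 3 and sham atrial array 4 were chosen after the data were seen; the other alternatives were planned.

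No count of probe sets after uninephrectomy left 0 under any alternative to filter, normalization, weights or covariate. Chamber counts moved with 1 probe set per gene, to 2725 in sham and 3550 in uninephrectomized dogs, and with a change of at least 1.5-fold, to 2884 and 3717, both by construction. Under quantile normalization they were 6439 (3004 higher and 3435 lower in the atrium, against 3367 and 2890) and 8182 (3886 and 4296, against 4429 and 3761), so the majority direction depends on the normalization, and with the gap as a covariate 6614 and 9070. With each array left out in turn, counts ranged from 0 to 1 in the atrium (1 without sham atrial array 5), 0 to 4 in the ventricle (4 without sham ventricular array 1, 1 without uninephrectomized ventricular array 1 and 1 without array 4), 0 to 0 for the difference, 5244 to 6345 in sham and 7046 to 8433 in uninephrectomized dogs.

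For lists, an estimated correlation called 0 in the atrium, 0 in the ventricle, 0 for the difference and 5 and 5 for the chambers in sham and uninephrectomized dogs. Fry called 0, 0 and 0 after uninephrectomy and 14 and 17 for the chambers of sham and uninephrectomized dogs. Exact permutation called 0 and 0 after uninephrectomy and 14 and 19 for the chambers. The preset fixes the correlation between genes at 0.01, which these tests do not. The gap as a covariate called 5 for the difference; the cause was not tested. With each array left out, list counts ranged from 1 (without sham atrial array 1) to 7 (without sham atrial array 5) in the atrium, and from 1 (without sham ventricular array 1, 2 or 5 or uninephrectomized ventricular array 2, 3 or 5) to 3 in the ventricle. For the difference they ranged from 1 (without uninephrectomized atrial array 4) to 6 (without sham atrial array 5), with 5 without uninephrectomized atrial array 1, sham ventricular array 3 or uninephrectomized ventricular array 1. They ranged from 10 to 11 and 10 to 13 for the chambers.

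With the replicate number as a fixed block the chamber counts were 5968 and 6686, as a random block 7035 and 9010, and with a block for the sham numbers alone 8030 and 8181; after uninephrectomy they stayed at 0. The blocked fits moved no count by over 1.5 times. Same-numbered uninephrectomized arrays correlated at -0.06, -0.07, 0.11, -0.24 and 0.10 across probe sets, 0 of 5 best with its own number, so they share only a number. Of the named genes, the blocks and other alternatives ended the call of 13 of 123 called in sham and 14 of 130 called in uninephrectomized chambers at least once, and 0 reversed. A pseudocount alternative was not run, since the values are on a log2 scale. Dim signal limits 41.3% of tested probe sets, whose mean lay under log2 3 in each group.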

Other observations

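The test of the lists in this part was chosen after the values were seen.

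Some genes differed strongly between sham dogs in both chambers. DECR1, a mitochondrial reductase of fatty acid oxidation, ranged from 5.01 to 10.69 among sham atria and from 5.69 to 10.88 among sham ventricles; among uninephrectomized atria it ranged from 5.20 to 10.37. ISG15, an interferon-induced modifier, ranged from 5.55 to 9.65 among sham atria and from 6.37 to 10.10 among sham ventricles, and from 7.45 to 9.18 among uninephrectomized atria. These genes belong to 151 probe sets, of 95 genes, whose sham atrial and ventricular arrays of the same number correlated above 0.9 and ranged over more than 1.5 log2 in both chambers. In uninephrectomized dogs 87 of the 151 had a correlation under 0 between arrays of the same number and 2 had a correlation above 0.9, against 82 above 0.9 in the order weighed above, which is a hypothesis.

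Of 7 interferon response genes that vary that widely, 6 are in this set (IFI44L, IFIH1, ISG15, MX1, OAS1 and OAS2), where 2.14 are expected among 311 genes (Fisher exact p = 0.00381, adjusted p = 0.0305 over 8 lists). These genes are not independent of each other. Of the fatty acid oxidation genes 1 of 3 was in the set.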
